A study of Rattus norvegicus with 44 samples.

How the data were processed

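Liver RNA of male Wistar rats was measured on Affymetrix rat expression arrays, 1 array per sample, 44 in all. The labels describe oral dosing by gavage once daily, killing 24 h after the last dose, a slice of the left lateral lobe kept in RNAlater, RNA extraction with RNeasy and labelling as biotinylated cRNA. Per the labels, the authors made the deposited intensity values with MAS5, whose version and scaling target the labels do not give. The deposited intensity of every array had the same sorted values (largest difference between sorted arrays 0, median 14.5, range 0.056 to 13236). The values had therefore been quantile normalized over all 44 arrays, a step the labels do not state, and compound, time and study were scaled together. Levels are therefore relative within an array. Detection calls were not used here, and signal over background sets the precision of dim genes.

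Of 8799 probe sets, 59 controls were left out. Gene symbols came from a table of the array's probe sets: 7017 probe sets had 1 symbol, 297 several and 1426 none in it, and genes are named from probe sets with 1 symbol. Each gene is represented by its probe set with the highest mean. Members of near-identical families, such as Cyp3a, Cyp2b, Cyp4a, Gsta and Ugt genes, can share signal on this array, so values given for 1 of them are uncertain as to the member. Cyp2b1 and Gpnmb were not tested by name, and some other genes of the naming rule are not reported here.

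The offset of 2.89, the percentile 20 of all values, was added before log2. Probe sets were tested when the highest group mean reached 9.17, the percentile 40, which left 6361 probe sets and 3698 genes. A linear model with 1 mean per group over the 11 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, 33 residual degrees of freedom and 2-sided p-values. The Benjamini-Hochberg adjustment ran within each of 14 comparisons, and a probe set was called at an adjusted p under 0.05. The comparisons were each dose with the vehicle of its study, the highest with the lowest dose in studies 1 and 2, the effect of the 30 and 100 mg/kg/day doses between times, R2 with R1, and vehicles between studies of the same time. Studies of different compound, time or dose used different arrays and vehicles, so a comparison across studies holds study differences too. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

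From knowledge of liver biology, 35 gene lists were fixed, of which 34 had enough genes on the array. They were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The mean log2 signal of a list's genes is its score. Genes were named by rule: up to 10 largest rises and falls with no overlap between groups, up to 4 called members per list, and a set of well-known liver genes, and the text gives a part of these. The design, this rule, the lists and a set of alternatives were fixed before the data were examined. That set held other scalings, offsets and filters, each study fitted alone, no trend, a replicate block, 1 probe set per gene, an estimated correlation, the mean over the probe sets of a gene, and each array left out in turn. Other splits of the compared arrays, at most 100 per comparison, or shuffles of the residuals for differences between effects, gave the calls of regrouped arrays. Arrays weighted by quality, centring on the tested probe sets, and R2 without replicates 1 and 2 were chosen after seeing the data.

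In simulated data with each probe set's mean and residual spread, 200 of 6361 probe sets were changed. For R1 10 and R1 30 at 24 h the procedure recovered 43% and 39% of 2-fold and 91% and 86% of 4-fold changes. At R1 20 after 336 h it recovered 61% and 98%, and with R2 54% and 95%. False calls were 14 of 148 for R1 10, a share over 0.05. Elsewhere they were 4 to 8 of 130 to 167, and 0 calls in all had the wrong sign.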

Results

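Liver RNA of male Wistar rats was profiled on 44 arrays in 4 separate studies of compounds R1 and R2, which the labels give by code name only. Rats received a compound or its vehicle, a citric acid buffer, by mouth once daily, and livers were taken after 24 h or after 336 h. In study 1 (24 h) there were 3 vehicle arrays, 4 at 10 mg/kg/day of R1, 3 at 30 and 3 at 100. Study 2 (336 h) had 4 vehicle arrays, 5 at 20 mg/kg/day of R1 and 4 at 100. Study 3 (336 h) had 5 vehicle arrays and 4 at 30 mg/kg/day of R1, and study 4 (24 h) had 4 vehicle arrays and 5 at 300 mg/kg/day of R2. The labels number the arrays of a group as replicates without saying more about their origin, so p-values measure the spread between these samples, which may be partly technical, and the number of arrays limits the precision.

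Arrays of a group correlated between 0.924 and 0.974 over the 6361 probe sets tested, and no pair of arrays was close enough to be taken for the same sample. Values below are log2 fold changes ± SE from limma on log2(signal + 2.89) unless another measure is named, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Because of the offset these values understate the change of dim genes. For a gene list, the mean log2 fold change over its genes is given with the adjusted p of limma's camera test, which sets the list against all other genes. This p assumes a correlation of 0.01 between genes and can be far smaller than with an estimated one, so its size does not rank evidence. List calls given with 1 p also held with an estimated correlation, and where that ended a call its p is printed.

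The first question was what R1 did to the liver within 24 h at rising doses. At 10 mg/kg/day, genes of cholesterol synthesis rose: 10 of 15 genes (12 adjusted over the list alone) were higher and the list's mean was 1.24 (adjusted p = 9.61e-31). They were led by Idi1 (2.66 ± 0.35), Acat2 (2.56 ± 0.37), Lss (1.64 ± 0.22) and Sqle (1.59 ± 0.34), which encode isopentenyl-diphosphate isomerase, an acetoacetyl-CoA thiolase, lanosterol synthase and squalene epoxidase. Genes known as targets of the drug-sensing receptors CAR and PXR rose as well (5 of 16 genes, 8 adjusted over the list alone, mean 0.84, adjusted p = 1.15e-14), among them the transporter Slco1a4 (2.06 ± 0.29), the drug oxidases Cyp3a23-3a1 (1.78 ± 0.18) and Cyp3a18 (1.64 ± 0.22), and Por (1.94 ± 0.38), the reductase that serves cytochromes P450. Of the targets of the oxidative stress factor NRF2, 3 of 13 genes (4 adjusted over the list alone) rose (mean 0.62, adjusted p = 1.54e-08), including Gclc (1.21 ± 0.24) and Gsr (1.20 ± 0.23) of glutathione metabolism and Akr7a3 (1.38 ± 0.35).

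Genes outside these lists included the falls of Slc6a6 (-1.84 ± 0.45), the taurine transporter, Mmp14 (-1.06 ± 0.22), a membrane metalloproteinase, C9 (-0.80 ± 0.18), a complement component, Igfals (-1.03 ± 0.27) and Papss2 (-1.14 ± 0.28), and the rise of Mcpt1l1 (2.03 ± 0.51), a mast cell protease. Lists of proteasome subunits (mean 0.33, adjusted p = 9.11e-06), interferon-response genes (mean -0.50, adjusted p = 0.0049) and acute phase proteins (mean -0.19, adjusted p = 0.0435) shifted with no single member called. Adjusted p was 0.0847, 0.242 and 0.531 with an estimated correlation, in the same order. In all, 79 of 6361 probe sets were called, 66 higher and 13 lower. Without vehicle replicate 1 or 2 the count was 44 or 37. Leaving out 1 array, vehicle replicate 2, ended the calls of Sqle, Por, Gsr and C9 (adjusted p up to 0.0844, 0.0595, 0.0544 and 0.115). Without R1 replicates 1 or 2 or vehicle replicates 1, 2 or 3, Akr7a3 and Igfals lost significance too (adjusted p up to 0.152 and 0.255). Slc6a6 (without R1 replicates 1 or 2 or vehicle replicates 1 or 2, adjusted p up to 0.181) and Mmp14 (without vehicle replicate 1, adjusted p up to 0.0697) likewise did. Papss2 (without R1 replicate 1 or vehicle replicates 1, 2 or 3, adjusted p up to 0.204) did too. Mcpt1l1 (without R1 replicates 1, 2, 3 or 4 or vehicle replicates 1, 2 or 3, adjusted p up to 0.115) also did. Other settings ended calls, with a smaller offset for Slc6a6 and with each study fitted alone for Mmp14 and Papss2. Leaving out 1 array also ended the list calls of interferon genes (without R1 replicates 3 or 4 or vehicle replicate 3, adjusted p up to 0.0775) and acute phase proteins (without R1 replicates 1, 2 or 3 or vehicle replicates 2 or 3, adjusted p up to 0.222).

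At 30 mg/kg/day of R1 after 24 h, cholesterol synthesis genes rose in 13 of 15 genes (15 adjusted over the list alone) with a mean of 2.34 (adjusted p = 8.44e-67). Idi1 (4.31 ± 0.37), Acat2 (4.10 ± 0.40), Sqle (3.60 ± 0.36) and Lss (2.69 ± 0.24) led again, followed by Msmo1 (2.55 ± 0.25), Mvd (2.53 ± 0.40), Cyp51 (2.28 ± 0.24) and Hsd17b7 (2.19 ± 0.31). CAR and PXR targets rose in 9 of 16 genes (11 adjusted over the list alone, mean 1.24, adjusted p = 4.24e-24), with Slco1a4 (2.54 ± 0.31), Por (2.12 ± 0.40), Cyp3a23-3a1 (2.07 ± 0.20) and Aldh1a1 (1.91 ± 0.36) at the top and Cyp2b2 (1.29 ± 0.35) below them. The signal of Cyp3a23-3a1 was 10598 with an SD of 0 in these treated arrays, near the top of the common scale, where rank sets the value and limits its fold change in every comparison. NRF2 targets rose in 4 of 13 genes (8 adjusted over the list alone, mean 0.93, adjusted p = 1.75e-13), led by Gclc (1.40 ± 0.25), Gsr (1.40 ± 0.24) and Txnrd1 (0.95 ± 0.25).

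Cell cycle genes rose as a list (mean 0.74, adjusted p = 2.81e-08), with 3 of 17 genes (7 adjusted over the list alone) called, namely the replication licensing genes Mcm6 (1.90 ± 0.41) and Mcm7 (0.95 ± 0.26) and cyclin D1, Ccnd1 (1.19 ± 0.30). Of the tested probe sets, only 1 of 3 was called for Mcm6 and 2 of 5 for Ccnd1. Proteasome subunits rose too (mean 0.47, adjusted p = 3.22e-10, 2 of 20 genes, 9 adjusted over the list alone), among them Psmc4 (0.97 ± 0.19) and Psmc3 (0.87 ± 0.23). Amino acid catabolism fell in 2 of 21 genes (5 adjusted over the list alone), Sds (-3.04 ± 0.80), serine dehydratase, and Ass1 (-0.75 ± 0.16) of the urea cycle (mean -0.59, adjusted p = 5.68e-08, but adjusted p = 0.106 with an estimated correlation). The p53 list, with Mdm2 (1.45 ± 0.30) as its 1 called gene, shifted up (mean 0.50, adjusted p = 0.022, but adjusted p = 0.106 with an estimated correlation). For Mdm2 and likewise for Sds, only 1 of 3 tested probe sets was called. Tsc22d1 (-2.23 ± 0.50), outside the lists, and Mx1 (-1.58 ± 0.43), an interferon-induced antiviral gene, fell. The test called 110 probe sets, 94 higher and 16 lower, or 73 without vehicle replicate 1. Without 1 array the test no longer called Cyp2b2 (without R1 replicate 1 or vehicle replicates 1, 2 or 3, adjusted p up to 0.37). Without R1 replicates 1 or 2 or vehicle replicates 1 or 2, Txnrd1 and Sds also lost significance (adjusted p up to 0.228 and 0.198). Mcm6 (without R1 replicate 1, adjusted p up to 0.0683) did too. Mcm7 (without R1 replicate 2 or vehicle replicates 1, 2 or 3, adjusted p up to 0.416) also did. Ccnd1 (without R1 replicate 1 or vehicle replicates 1 or 2, adjusted p up to 0.185) likewise did. Psmc3 (without R1 replicates 1 or 3 or vehicle replicates 1, 2 or 3, adjusted p up to 0.233) did too. Without vehicle replicate 1, Ass1 and Tsc22d1 likewise did (adjusted p up to 0.0814 and 0.122). Mx1 (without R1 replicates 1 or 2 or vehicle replicates 1, 2 or 3, adjusted p up to 0.279) also lost significance. Further calls ended with weighted arrays for Cyp2b2, Mcm7 and Mx1, with no filter on dim probe sets for Cyp2b2, Mcm7 and Mx1, with each study fitted alone for Mcm7 and Mx1 and with a smaller offset for Mcm7. Without 1 array the list call also ended for p53 targets (without R1 replicate 1 or vehicle replicate 1, adjusted p up to 0.152).

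At 100 mg/kg/day after 24 h, 14 of 15 genes (15 adjusted over the list alone) of the cholesterol list were higher (mean 2.61, adjusted p = 4.69e-51), with Idi1 (4.75 ± 0.37), Acat2 (4.42 ± 0.40), Sqle (3.94 ± 0.36), Mvd (3.34 ± 0.40) and Lss (3.01 ± 0.24) in front. Idi1 signal was 3749 ± 335.3 (SD, n = 3) against 138.6 ± 31.1 (SD, n = 3) in vehicle. CAR and PXR targets rose in 10 of 16 genes (13 adjusted over the list alone, mean 1.39, adjusted p = 2.09e-20), with Slco1a4 (2.34 ± 0.31), Por (2.28 ± 0.40), Cyp3a23-3a1 (2.20 ± 0.20) and Aldh1a1 (2.08 ± 0.36). NRF2 targets rose in 9 of 13 genes (10 adjusted over the list alone, mean 1.15, adjusted p = 1.00e-12). These included heme oxygenase, Hmox1 (2.06 ± 0.31), malic enzyme, Me1 (1.96 ± 0.42), and the glutathione genes Gpx2 (1.64 ± 0.48), Gsr (1.51 ± 0.24) and Gclc (1.38 ± 0.25).

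Proteasome subunits rose in 13 of 20 genes (19 adjusted over the list alone) with a mean of 0.91 (adjusted p = 2.23e-22), led by Psma5 (1.32 ± 0.19), Psmc4 (1.29 ± 0.19) and Psmb3 (1.19 ± 0.22). Amino acid catabolism fell in 8 of 21 genes (10 adjusted over the list alone, mean -0.76, adjusted p = 3.47e-09, but adjusted p = 0.089 with an estimated correlation), including Sds (-2.95 ± 0.80), Cth (-1.58 ± 0.28), Bhmt (-1.27 ± 0.33) and Gls2 (-1.25 ± 0.27). Glucose handling genes fell in 4 of 12 genes (5 adjusted over the list alone, mean -0.48, adjusted p = 0.0135, but adjusted p = 0.112 with an estimated correlation), with Pfkfb1 (-1.30 ± 0.37) and Slc37a4 (-1.07 ± 0.24). Srebf1 (-2.03 ± 0.40), a regulator of fatty acid synthesis, and Scd (-1.85 ± 0.56), stearoyl-CoA desaturase, fell, while their list was not called (mean -0.25, adjusted p = 0.775). Other falls were Cyp17a1 (-2.69 ± 0.49), a steroid hydroxylase, Tsc22d1 (-3.07 ± 0.50) and Slc6a6 (-2.03 ± 0.49). The p53 targets Mdm2 (1.99 ± 0.30) and Gadd45a (1.29 ± 0.30) rose (list mean 0.56, adjusted p = 0.0201, but adjusted p = 0.106 with an estimated correlation). Fatty acid oxidation genes shifted slightly up (mean 0.32, adjusted p = 0.0135, but adjusted p = 0.0922 with an estimated correlation), with Acot2 (2.95 ± 0.66) and Ech1 (0.99 ± 0.18) called.

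Smaller list shifts did not hold with an estimated correlation. Heat shock proteins (mean 0.43, adjusted p = 0.0242), immediate early genes (mean 0.48, adjusted p = 0.0201) and female-predominant liver genes (mean 0.73, adjusted p = 0.0436) were up. Adjusted p was 0.211, 0.222 and 0.211 with an estimated correlation, in the same order. Oxidative phosphorylation genes were down (mean -0.29, adjusted p = 0.0135, but adjusted p = 0.106 with an estimated correlation). The test called 407 probe sets, 252 higher and 155 lower. The count was 271 without R1 replicate 1 and 263 without vehicle replicate 1, and 633 with arrays weighted by quality, an alternative chosen after the data were seen. The calls that leaving out 1 array ended included those of Gpx2 (without R1 replicates 2 or 3 or vehicle replicates 2 or 3, adjusted p up to 0.159). Without R1 replicates 1 or 3 or vehicle replicates 1 or 2, Sds and Pfkfb1 lost significance (adjusted p up to 0.0809 and 0.138). Bhmt (without R1 replicate 1 or vehicle replicate 1, adjusted p up to 0.0885) did too. Scd (without R1 replicate 2 or vehicle replicates 1, 2 or 3, adjusted p up to 0.303) and Gadd45a (without R1 replicate 1, adjusted p up to 0.0592) also lost significance. Without 1 array list calls ended for heat shock proteins (without R1 replicate 1 or vehicle replicate 3, adjusted p up to 0.208). The p53 targets (without vehicle replicate 1, adjusted p up to 0.0514) and immediate early genes (without R1 replicate 1 or vehicle replicate 1, adjusted p up to 0.0588) also lost significance. Female-predominant genes (without R1 replicates 1 or 2 or vehicle replicate 2, adjusted p up to 0.182) lost significance too.

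A direct test of 100 against 10 mg/kg/day within study 1 called 253 probe sets, 147 higher and 106 lower. The cholesterol list was higher at 100 in 13 of 15 genes (13 adjusted over the list alone, mean 1.36, adjusted p = 3.48e-24), as were proteasome subunits (9 of 20 genes, 16 adjusted over the list alone, mean 0.58, adjusted p = 7.72e-14) and CAR and PXR targets (2 of 16 genes, 3 adjusted over the list alone, mean 0.56, adjusted p = 8.24e-05). Fatty acid oxidation genes (mean 0.40, adjusted p = 6.18e-04) and female-predominant genes (mean 1.11, adjusted p = 0.00196) were higher, and amino acid catabolism (mean -0.67, adjusted p = 3.58e-11), glucose handling (mean -0.52, adjusted p = 0.00104) and oxidative phosphorylation (mean -0.27, adjusted p = 0.00196) lower. The NRF2 difference (mean 0.53, adjusted p = 0.00104) did not hold, adjusted p = 0.0681 with an estimated correlation. Hmox1 (1.77 ± 0.29), Mdm2 (1.68 ± 0.28) and Ccnd1 (1.56 ± 0.28) were higher at 100 and Srebf1 (-2.76 ± 0.37) and Cth (-1.66 ± 0.26) lower. The count was 157 or 160 without replicate 1 or 2 of the 10 mg/kg group, 124 without replicate 1 of the 100 mg/kg group, and 380 with weighted arrays.

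**Figure D1:**
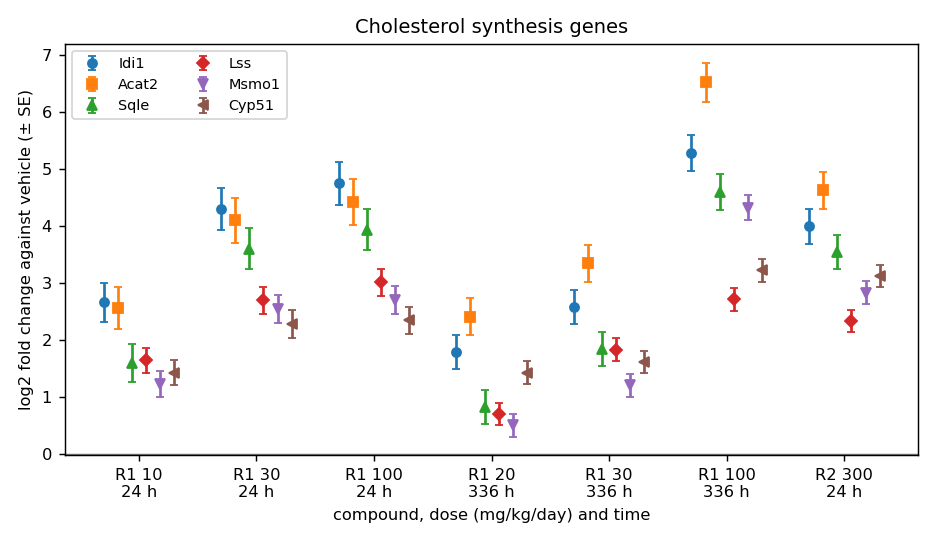
Log2 fold change against the vehicle of the same study (y axis, bars ± SE) for 6 cholesterol synthesis genes, by compound, dose in mg/kg/day and time (x axis). Idi1 moved from 2.66 at R1 10 to 4.75 at R1 100 after 24 h, and Acat2 reached 6.53, from a dim vehicle, at R1 100 after 336 h.

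The studies of 336 h asked what repeated dosing did. At 20 mg/kg/day of R1 in study 2, drug metabolism genes rose: 9 of 16 genes (12 adjusted over the list alone) of the CAR and PXR list were higher and 1 lower (mean 1.41, adjusted p = 1.57e-23), led by Cyp3a23-3a1 (3.05 ± 0.16), Abcc3 (2.71 ± 0.32), Slco1a4 (2.67 ± 0.26), Akr7a3 (2.43 ± 0.31) and Cyp2b2 (2.17 ± 0.28). NRF2 targets rose in 7 of 13 genes (10 adjusted over the list alone, mean 1.31, adjusted p = 9.47e-18), among them the glutathione peroxidase Gpx2 (3.05 ± 0.39) and the glutathione transferase Gstp1 (2.63 ± 0.23). Among the largest rises were also the glutathione transferases Gsta3 (4.65 ± 0.38) and Gstm5 (2.62 ± 0.36), Ggt1 (3.91 ± 0.25), gamma-glutamyltransferase, and Ddc (3.19 ± 0.21), dopa decarboxylase. The vehicle signal of Ddc was 3.78 ± 0.512 (SD, n = 4) in study 2 and 135.1 ± 23.0 (SD, n = 5) in study 3. Ggt1 signal was 71.7 ± 25.1 (SD, n = 5) against 1.89 ± 0.644 (SD, n = 4). Vehicle means of Ggt1, Ddc, Gstm5 (4.92), Abcc3 (4.54) and Acat2 (5.72) lay under the filter level of 9.17, so their rises are of uncertain size. The cholesterol list was higher (mean 0.62, adjusted p = 1.97e-06, but adjusted p = 0.091 with an estimated correlation), with 6 of 15 genes (9 adjusted over the list alone) higher, such as Acat2 (2.41 ± 0.33), Idi1 (1.79 ± 0.30) and Cyp51 (1.42 ± 0.20), and 1 lower.

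Immediate early genes fell as a list (mean -1.08, adjusted p = 6.74e-06), with 3 of 11 genes (6 adjusted over the list alone) called, Egr1 (-4.84 ± 0.63), Dusp1 (-2.23 ± 0.48) and Jun (-1.39 ± 0.30). Egr1 signal was 1764 ± 965.0 (SD, n = 4) in this vehicle and 172.5 ± 122.2 (SD, n = 5) in that of study 3, and the list score was 6.06 and 5.72, with 4.98 at 20 mg/kg/day. The growth hormone and IGF list fell (mean -0.76, adjusted p = 6.26e-05, 2 of 8 genes, 6 adjusted over the list alone), with Igfals (-1.16 ± 0.24) and Igfbp3 (-0.84 ± 0.25). The list of PPAR-alpha targets and fatty acid oxidation shifted down (mean -0.26, adjusted p = 0.002), although Cyp4a8 (1.30 ± 0.37) rose and Ehhadh (-0.88 ± 0.22) was the called fall, from a vehicle score of 7.89 where the vehicle of study 3 had 6.65. Apoa4 (-2.69 ± 0.38), an apolipoprotein, Cyp17a1 (-2.24 ± 0.41), Scd (-1.69 ± 0.46) and Hsd17b6 (-1.52 ± 0.23) fell as single genes.

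Lists that were lower but did not hold with an estimated correlation were amino acid catabolism (mean -0.39, adjusted p = 6.74e-06), acute phase proteins (mean -0.23, adjusted p = 0.00409) and glucose handling (mean -0.43, adjusted p = 0.0169). Adjusted p was 0.162 for each of them with an estimated correlation. The interferon response (mean -0.44, adjusted p = 0.0269), cytokines (mean -0.41, adjusted p = 0.0169) and Kupffer cell markers (mean -0.40, adjusted p = 0.0172) went the same way, with Irf7 (-1.54 ± 0.37) and Clec4f (-0.88 ± 0.22) called. Adjusted p was 0.226, 0.134 and 0.162 with an estimated correlation, in the same order. Proteasome subunits were higher (mean 0.22, adjusted p = 0.0137, but adjusted p = 0.226 with an estimated correlation). The test called 282 probe sets, 162 higher and 120 lower, and 452 with weighted arrays. Single arrays decided the calls of Igfbp3 (without R1 replicates 2, 4 or 5 or vehicle replicates 2 or 3, adjusted p up to 0.214). Cyp4a8 (without R1 replicates 1, 3 or 4 or vehicle replicates 1, 3 or 4, adjusted p up to 0.0944) also lost significance. Ehhadh (without R1 replicate 3 or vehicle replicate 2, adjusted p up to 0.076) and Scd (without vehicle replicate 3, adjusted p up to 0.185) lost significance too. Clec4f (without vehicle replicate 1, adjusted p up to 0.0552) likewise lost significance. Calls also ended with each study fitted alone for Igfbp3 and Scd. Single arrays also decided the list calls of cytokines (without R1 replicate 5, adjusted p up to 0.0829). Without R1 replicate 5 or vehicle replicate 1, interferon genes and Kupffer cell markers lost significance (adjusted p up to 0.22 and 0.143). The proteasome (without R1 replicate 1, adjusted p up to 0.0904) also did.

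At 100 mg/kg/day after 336 h, cholesterol synthesis rose in 14 of 15 genes (15 adjusted over the list alone, mean 3.17, adjusted p = 1.55e-51), led by Acat2 (6.53 ± 0.34), Idi1 (5.28 ± 0.32), Sqle (4.60 ± 0.32), Msmo1 (4.33 ± 0.21), Mvd (3.67 ± 0.35) and Fdft1 (3.30 ± 0.20). Acat2 signal was 819.6 ± 389.0 (SD, n = 4) against 5.72 ± 3.43 (SD, n = 4), under the filter level of 9.17, so the size of its rise is uncertain. PPAR-alpha targets and fatty acid oxidation fell in 18 of 25 genes (20 adjusted over the list alone) with none higher (mean -1.58, adjusted p = 5.34e-27). The acyl-CoA thioesterases Acot1 (-4.59 ± 0.44) and Acot2 (-3.45 ± 0.57), the omega-hydroxylase Cyp4a1 (-3.22 ± 0.41), the peroxisomal bifunctional enzyme Ehhadh (-3.08 ± 0.24), Ech1 (-2.83 ± 0.16) and the carnitine palmitoyltransferase Cpt1a (-2.64 ± 0.28) led this fall, and Eci1 (-3.10 ± 0.19) fell outside the list. Lipid droplet genes fell in 3 of 7 genes (4 adjusted over the list alone, mean -0.80, adjusted p = 0.00148), among them Plin2 (-2.44 ± 0.24), a coat protein of lipid droplets, and Mgll (-1.30 ± 0.28).

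The vehicle arrays of study 2 themselves stood apart from the other vehicles in these lists. Their fatty acid oxidation score, the mean log2 signal over the list, was 7.89 ± 0.13 (SD, n = 4), against 6.65 ± 0.15 (SD, n = 5) in the vehicle of study 3, 6.57 ± 0.04 (SD, n = 3) in study 1 and 6.68 ± 0.04 (SD, n = 4) in study 4. At 20 and 100 mg/kg/day in study 2 it was 7.62 ± 0.16 (SD, n = 5) and 6.31 ± 0.06 (SD, n = 4). Their cholesterol score was 5.99 ± 0.22 (SD, n = 4) against 7.64 ± 0.09 (SD, n = 5) in study 3, and at 100 mg/kg/day it was 9.16 ± 0.44 (SD, n = 4).

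NRF2 targets rose in 11 of 13 genes (11 adjusted over the list alone, mean 1.55, adjusted p = 2.04e-16), with Gstp1 (3.02 ± 0.25), Gpx2 (2.75 ± 0.41) and Nqo1 (1.94 ± 0.55). CAR and PXR targets rose in 9 of 16 genes (9 adjusted over the list alone, mean 1.17, adjusted p = 1.01e-10), with Cyp3a23-3a1 (3.10 ± 0.17), Abcc3 (3.03 ± 0.33), Slco1a4 (2.99 ± 0.27) and Ugt2b1 (2.51 ± 0.33). Gsta3 (4.76 ± 0.40), Ggt1 (4.32 ± 0.26) and Ddc (3.84 ± 0.22) were again among the largest rises. The growth hormone and IGF list fell in 4 of 8 genes (5 adjusted over the list alone, mean -0.78, adjusted p = 8.59e-04), including Igfbp3 (-1.86 ± 0.26), Igf1 (-0.89 ± 0.20) and Ghr (-0.87 ± 0.19). The male-predominant genes Obp3 (-4.45 ± 0.45) and Cyp2c11 (-3.40 ± 0.36) fell, and so did Cyp17a1 (-3.96 ± 0.43), while the male-predominant list as a whole was not called (mean -0.95, adjusted p = 0.0859). Amino acid catabolism was lower (mean -0.50, adjusted p = 5.96e-04), with Asl (-1.70 ± 0.19), Hal (-1.52 ± 0.21) and Agxt (-1.47 ± 0.21), and proteasome subunits were higher (mean 0.28, adjusted p = 0.0164). Adjusted p was 0.33 for each of them with an estimated correlation. The test called 656 probe sets, 325 higher and 331 lower. The call that ended on leaving out 1 array was that of Nqo1 (without R1 replicates 2 or 4 or vehicle replicate 1, adjusted p up to 0.103). List calls that ended on leaving out 1 array were those of amino acid catabolism (without R1 replicate 3, adjusted p up to 0.0789) and the proteasome (without R1 replicates 1, 3 or 4, adjusted p up to 0.0789).

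Set directly against 20 mg/kg/day in study 2, 100 mg/kg/day changed 259 probe sets, 133 higher and 126 lower. The cholesterol list was higher at 100 in 15 of 15 genes (15 adjusted over the list alone, mean 2.55, adjusted p = 7.71e-74), with Acat2 (4.12 ± 0.33), Msmo1 (3.82 ± 0.20) and Sqle (3.78 ± 0.30). Fatty acid oxidation was lower in 15 of 25 genes (20 adjusted over the list alone, mean -1.32, adjusted p = 8.97e-34), with Acot1 (-4.67 ± 0.42), Ech1 (-2.52 ± 0.15) and Cpt1a (-1.83 ± 0.27), and lipid droplet genes were lower (mean -0.76, adjusted p = 1.89e-05). Immediate early genes were higher (mean 0.81, adjusted p = 1.89e-05), among them Ier3 (1.55 ± 0.19), Jun (1.73 ± 0.30) and Dusp1 (1.72 ± 0.48). Fatty acid synthesis (mean 0.72, adjusted p = 6.33e-05), acute phase proteins (mean 0.26, adjusted p = 0.0267), p53 targets (mean 0.58, adjusted p = 0.0225) and male-predominant genes (mean -0.88, adjusted p = 0.00967) shifted without holding. Adjusted p was 0.0957, 0.377, 0.125 and 0.333 with an estimated correlation, in the same order. Obp3 (-4.04 ± 0.42) and Cyp2c11 (-2.86 ± 0.34) were lower at 100, and Gdf15 (2.20 ± 0.43), Fasn (2.13 ± 0.31) and Acly (2.38 ± 0.29) higher. A single array decided the call of Dusp1 (without study 2 R1 100 replicates 1, 2 or 3 or study 2 R1 20 replicates 3, 4 or 5, adjusted p up to 0.217). Weighted arrays and each study fitted alone also ended the call of Dusp1. For lists this was the case for acute phase proteins (without study 2 R1 100 replicate 2 or study 2 R1 20 replicates 1 or 4, adjusted p up to 0.201) and p53 targets (without study 2 R1 100 replicate 3, adjusted p up to 0.0933).

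**Figure D2:**
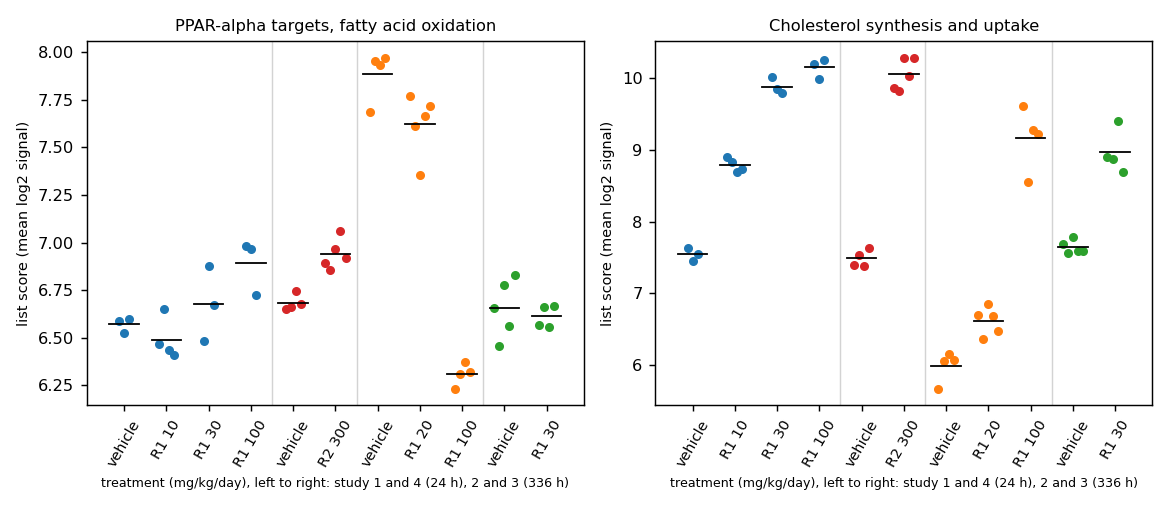
List scores (y axis, mean log2 signal over the list's genes) of each array for fatty acid oxidation (left) and cholesterol synthesis (right), by treatment group (x axis, doses in mg/kg/day), with points for arrays coloured by study and black bars for group means. The study 2 vehicle averaged 7.89 on the left and 5.99 on the right, and the study 3 vehicle 6.65 and 7.64.

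At 30 mg/kg/day of R1 after 336 h, in study 3, NRF2 targets rose in 10 of 13 genes (12 adjusted over the list alone, mean 1.64, adjusted p = 4.30e-18), with Gpx2 (4.18 ± 0.39), Gstp1 (3.71 ± 0.23) and Me1 (2.72 ± 0.35) in front. CAR and PXR targets rose in 11 of 16 genes (12 adjusted over the list alone) and fell in 1 (mean 1.49, adjusted p = 9.03e-18), led by the retinaldehyde dehydrogenase Aldh1a1 (4.01 ± 0.29), with Cyp2b2 (3.52 ± 0.28), Abcc3 (2.56 ± 0.32) and Ugt2b1 (2.22 ± 0.31). Ggt1 (4.24 ± 0.25), Gsta3 (3.62 ± 0.38), Sult2a2 (2.82 ± 0.31) and the antimicrobial peptide Defb1 (2.75 ± 0.42) were also among the largest rises. Ggt1 signal was 89.5 ± 24.2 (SD, n = 4) against 1.99 ± 1.18 (SD, n = 5), near the bottom of the scale. Cholesterol synthesis rose in 12 of 15 genes (13 adjusted over the list alone, mean 1.32, adjusted p = 9.03e-18), with Acat2 (3.34 ± 0.33), Idi1 (2.58 ± 0.30) and Sqle (1.84 ± 0.30). Proteasome subunits rose in 10 of 20 genes (14 adjusted over the list alone, mean 0.50, adjusted p = 2.61e-09), with Psmb1 (0.84 ± 0.14) and Psmc4 (0.67 ± 0.15).

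The growth hormone and IGF list fell in 5 of 8 genes (5 adjusted over the list alone, mean -0.50, adjusted p = 0.0046), with Socs2 (-1.64 ± 0.47), Igfbp3 (-1.30 ± 0.25) and Igf1 (-1.02 ± 0.19). Amino acid catabolism fell in 11 of 21 genes (12 adjusted over the list alone, mean -0.69, adjusted p = 8.24e-10, but adjusted p = 0.0569 with an estimated correlation), including Gnmt (-2.23 ± 0.31), Hal (-1.71 ± 0.20), Gls2 (-1.33 ± 0.22) and Agxt (-1.29 ± 0.20). Other large falls were Slc6a6 (-3.42 ± 0.40), Apoa4 (-3.34 ± 0.38), Hsd17b6 (-2.70 ± 0.23), Scd (-2.67 ± 0.46), Sgk1 (-2.42 ± 0.32) and Inhbe (-2.06 ± 0.23). Male-predominant genes were lower (mean -0.70, adjusted p = 0.0203, but adjusted p = 0.268 with an estimated correlation), with Hao2 (-1.92 ± 0.39), Obp3 (-1.42 ± 0.42) and Cyp2c11 (-1.10 ± 0.34). Fatty acid oxidation was not called (mean -0.04, adjusted p = 0.701).

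Markers of other cells moved in this comparison. Cholangiocyte markers were higher (mean 0.82, adjusted p = 0.0364, but adjusted p = 0.174 with an estimated correlation), with Cd24 (1.56 ± 0.36) and Epcam (1.30 ± 0.30) called. Erythroid and blood genes were lower (mean -0.75, adjusted p = 0.0287), as were pancreas and adipose markers, which would come with other tissue (mean -0.50, adjusted p = 0.0291), and lysosome genes were higher (mean 0.30, adjusted p = 0.0364), with Ctsd (1.49 ± 0.23) and Cd63 (1.47 ± 0.26). Adjusted p was 0.136, 0.136 and 0.174 with an estimated correlation, in the same order. The test called 717 probe sets, 335 higher and 382 lower, but 453 without R1 replicate 3. That array or another decided the calls of Socs2 (without vehicle replicates 1 or 4, adjusted p up to 0.0684) and Obp3 (without R1 replicates 1 or 3, adjusted p up to 0.228). Cyp2c11 (without R1 replicates 2 or 3 or vehicle replicates 1, 2 or 3, adjusted p up to 0.382) also lost significance. Other settings ended calls, with each study fitted alone for Cyp2c11. Without R1 replicate 3 the list calls of lysosome and male-predominant genes ended (adjusted p up to 0.055 and 0.154). Cholangiocyte markers (without R1 replicates 1 or 3 or vehicle replicate 3, adjusted p up to 0.0814) also lost significance. Erythroid genes (without R1 replicate 3 or vehicle replicate 5, adjusted p up to 0.085) did too. Pancreas and adipose markers (without R1 replicate 2 or vehicle replicate 3, adjusted p up to 0.0814) likewise did.

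**Figure D3:**
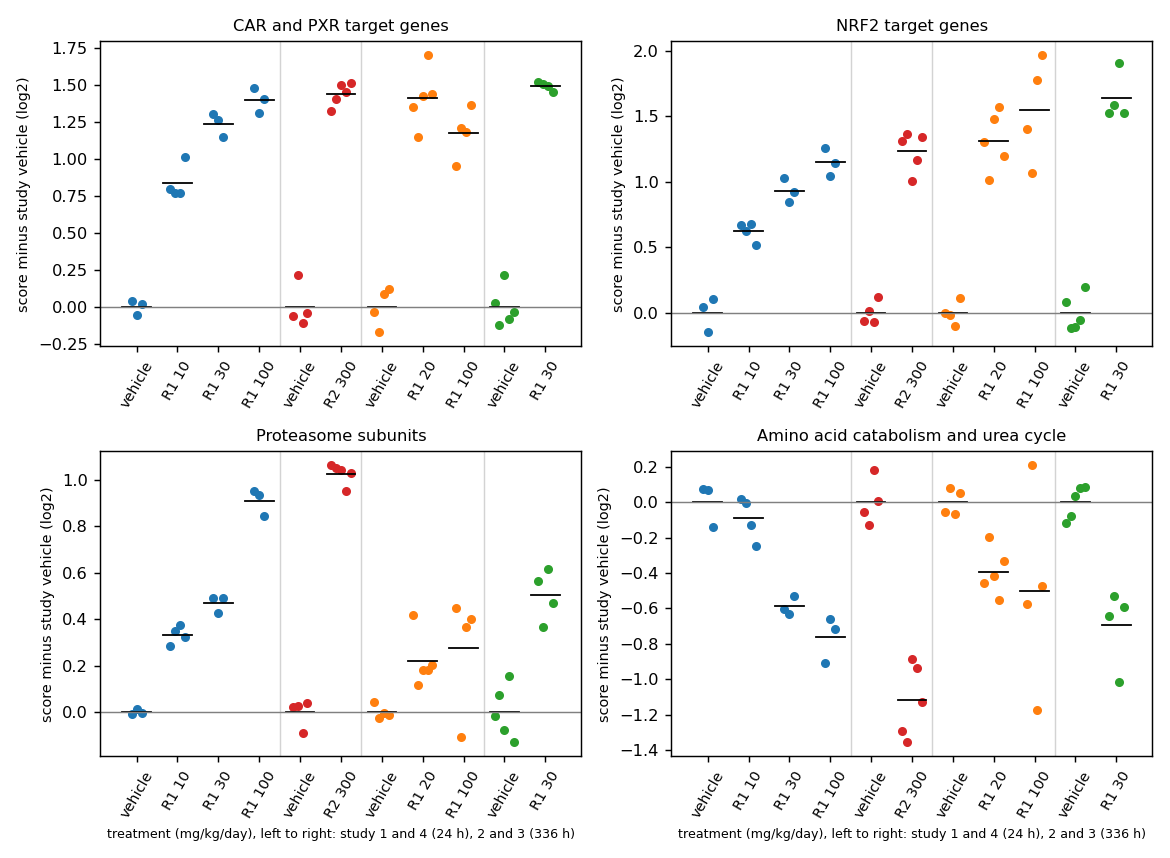
Scores of each array (y axis, mean log2 signal over a list minus the mean of the vehicle arrays of the same study) for 4 gene lists, by treatment group (x axis, doses in mg/kg/day), with points for arrays coloured by study and black bars for group means. At R2 300 the mean differences were 1.44 for CAR and PXR targets, 1.24 for NRF2 targets, 1.03 for the proteasome and -1.12 for amino acid catabolism.

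Whether the effect of a dose differed between times was tested as a difference of differences, in which study and time cannot be told apart. For 100 mg/kg/day, 337 probe sets differed, 138 with a higher effect at 336 h and 199 with a lower one. The effect on fatty acid oxidation was lower at 336 h in 17 of 25 genes (20 adjusted over the list alone, mean -1.90, adjusted p = 1.20e-29), as was that on the proteasome (mean -0.63, adjusted p = 2.93e-08). The effect, 336 h minus 24 h, was higher for Ddc (4.74 ± 0.34), Ggt1 (4.33 ± 0.40), Gsta3 (3.46 ± 0.61) and Gstp1 (2.36 ± 0.37) and lower for Acot1 (-4.59 ± 0.67), Ech1 (-3.82 ± 0.24), Cpt1a (-3.22 ± 0.43), Obp3 (-4.53 ± 0.68) and Por (-2.72 ± 0.53). Of the latter, Acot1, Ech1, Cpt1a and Obp3 fell at 336 h, whereas Por rose at 24 h and was at -0.44 ± 0.35 at 336 h, where it was not called. The vehicle score of fatty acid oxidation was 7.89 in study 2 and 6.57 in study 1, and these levels enter the values. So do those of Ddc, whose signal rose from 3.78 ± 0.512 (SD, n = 4) to 95.5 ± 29.9 (SD, n = 4) in study 2 and was 158.7 ± 9.85 (SD, n = 3) in the vehicle of study 1. At 30 mg/kg/day the same difference for Ddc was 0.66 ± 0.33 (adjusted p = 0.513), not called. Shifts of fatty acid synthesis (mean 0.85, adjusted p = 0.0241), lipid droplet genes (mean -0.86, adjusted p = 0.00767), cholesterol synthesis (mean 0.57, adjusted p = 0.0111), heat shock proteins (mean -1.04, adjusted p = 0.00138), the cell cycle (mean -0.51, adjusted p = 0.0287), growth hormone and IGF genes (mean -0.92, adjusted p = 0.0291) and oxidative phosphorylation (mean 0.28, adjusted p = 0.0311) did not hold. Adjusted p was 0.364, 0.084, 0.364, 0.084, 0.364, 0.084 and 0.267 with an estimated correlation, in the same order. Without 1 array the list calls that ended included fatty acid synthesis (without study 1 R1 100 replicate 2 or study 1 vehicle replicate 1 or study 2 R1 100 replicate 1, adjusted p up to 0.151). Cholesterol synthesis (without study 2 R1 100 replicate 1, adjusted p up to 0.0806) also lost significance. The cell cycle (without study 1 R1 100 replicate 2 or study 1 vehicle replicate 2 or study 2 R1 100 replicates 1 or 4, adjusted p up to 0.24) lost significance too. Growth hormone and IGF genes (without study 2 R1 100 replicates 1 or 4, adjusted p up to 0.107) likewise lost significance. Oxidative phosphorylation (without study 1 R1 100 replicate 2 or study 1 vehicle replicates 1 or 2 or study 2 R1 100 replicates 2, 3 or 4 or study 2 vehicle replicate 3, adjusted p up to 0.111) also lost significance.

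For 30 mg/kg/day, 61 probe sets differed between the times, 32 higher and 29 lower at 336 h. The effect was higher at 336 h for Ggt1 (4.40 ± 0.39), Gstp1 (3.41 ± 0.37), Gpx2 (3.22 ± 0.62), Cyp2b2 (2.23 ± 0.45) and Aldh1a1 (2.10 ± 0.46), and lower for Socs2 (-2.94 ± 0.73), Apoa4 (-2.83 ± 0.60) and Hsd17b6 (-1.93 ± 0.36), which fell at 336 h and were not called at 24 h (1.30 ± 0.57, -0.52 ± 0.47 and -0.78 ± 0.28). The effect on cholesterol synthesis was lower at 336 h (mean -1.01, adjusted p = 2.84e-12, 1 gene called and 12 adjusted over the list alone), and so was that on erythroid genes (mean -1.23, adjusted p = 2.84e-04). NRF2 targets (mean 0.70, adjusted p = 0.005), lysosome genes (mean 0.34, adjusted p = 0.0244), the cell cycle (mean -0.64, adjusted p = 6.25e-04), growth hormone and IGF genes (mean -0.57, adjusted p = 0.0175) and stellate cell markers (mean -0.46, adjusted p = 0.0263) did not hold. Adjusted p was 0.192, 0.192, 0.216, 0.0656 and 0.34 with an estimated correlation, in the same order. The count was 34 without the 24 h R1 replicate 1, and 30 or 35 without vehicle replicate 1 or 2 of study 1. Calls that ended without 1 array included those of Aldh1a1 (without study 1 R1 30 replicate 3 or study 1 vehicle replicates 1 or 3, adjusted p up to 0.0768). Socs2 (without study 1 R1 30 replicate 3 or study 1 vehicle replicates 1 or 3 or study 3 R1 30 replicates 1, 2 or 4 or study 3 vehicle replicates 1 or 4, adjusted p up to 0.182) also lost significance. Apoa4 (without study 1 R1 30 replicate 1, adjusted p up to 0.051) lost significance too. That of Socs2 also ended with no filter on dim probe sets. List calls ended without 1 array for lysosome genes (without study 1 R1 30 replicate 1 or study 1 vehicle replicate 3, adjusted p up to 0.129) and stellate cell markers (without study 1 R1 30 replicate 3 or study 1 vehicle replicate 2 or study 3 R1 30 replicate 3 or study 3 vehicle replicate 2, adjusted p up to 0.223).

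The 336 h studies used separate vehicle arrays, so their calls could be compared without shared controls. R1 at 100 mg/kg/day (study 2) and at 30 (study 3) had 160 probe sets higher in both, where independent lists would share 17.1, 114 lower in both (expected 19.9) and 12 called in opposite directions (expected 36.9). For 20 and 30 mg/kg/day these numbers were 116 (expected 8.53), 72 (expected 7.21) and 4 (expected 16.0). The 24 h arrays had vehicles of their own too. For 30 mg/kg/day at 24 and 336 h the numbers were 74 higher in both (expected 4.95), 9 lower in both (expected 0.961) and 1 opposite (expected 6.49). For 100 mg/kg/day at these times they were 100 higher in both (expected 12.9), 26 lower in both (expected 8.07) and 23 opposite (expected 21.0), and for R1 100 at 336 h with R2 at 24 h 128 higher in both (expected 24.2), 72 lower in both (expected 26.1) and 52 opposite (expected 50.2), so in these 2 pairs opposite calls were not fewer than from independent lists.

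Vehicle groups of the same time were compared to show how far the studies themselves lay apart. At 336 h, fatty acid oxidation was lower in study 3 than in study 2 in 13 of 25 genes (14 adjusted over the list alone), with 2 higher (mean -1.23, adjusted p = 8.49e-14), led by Acot1 (-4.64 ± 0.42), Ech1 (-4.00 ± 0.15), Cpt1a (-3.29 ± 0.27) and Cyp4a1 (-2.87 ± 0.39). Cholesterol synthesis was higher in 14 of 15 genes (14 adjusted over the list alone, mean 1.65, adjusted p = 6.60e-20), with Acat2 (3.40 ± 0.33), Sqle (2.49 ± 0.30) and Idi1 (2.01 ± 0.30). Ddc (4.36 ± 0.21), Scd (2.60 ± 0.46) and Fasn (1.92 ± 0.31) were higher in study 3 and Cyp17a1 (-3.58 ± 0.41) and Egr1 (-3.49 ± 0.63) lower. Fatty acid synthesis (mean 1.08, adjusted p = 1.01e-04), heat shock proteins (mean -0.82, adjusted p = 0.0178) and the proteasome (mean -0.41, adjusted p = 1.53e-05) shifted without holding. Adjusted p was 0.129, 0.276 and 0.12 with an estimated correlation, in the same order. In all 1135 probe sets differed, 544 higher and 591 lower in study 3, more than in any comparison of R1 or R2 with its vehicle.

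At 24 h, no list was called between the vehicles of studies 4 and 1 (smallest adjusted p 0.137). Socs2 (2.52 ± 0.53), a growth hormone target, and Dusp1 (2.36 ± 0.55) and Gadd45a (1.16 ± 0.28) were higher in study 4, and Cyp2b2 (-1.70 ± 0.32) was lower. The test called 359 probe sets, 167 higher and 192 lower. The count was 221 or 193 without vehicle replicate 1 or 2 of study 1 and 714 with weighted arrays. Without study 1 vehicle replicate 1 the calls of Dusp1 and Gadd45a ended (adjusted p up to 0.0922 and 0.0644).

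R2 was given at 300 mg/kg/day for 24 h. Cholesterol synthesis rose in 13 of 15 genes (15 adjusted over the list alone, mean 2.56, adjusted p = 8.43e-39), led by Acat2 (4.62 ± 0.33), Idi1 (3.99 ± 0.30), Sqle (3.54 ± 0.30), Mvd (3.44 ± 0.33) and Cyp51 (3.13 ± 0.20). Proteasome subunits rose in 18 of 20 genes (20 adjusted over the list alone, mean 1.03, adjusted p = 6.80e-24), with Psmc4 (1.49 ± 0.15), Psmc5 (1.35 ± 0.16) and Psma5 (1.31 ± 0.16). CAR and PXR targets rose in 13 of 16 genes (14 adjusted over the list alone, mean 1.44, adjusted p = 1.66e-17), with Aldh1a1 (2.42 ± 0.29), Cyp3a23-3a1 (2.29 ± 0.16), Cyp2b2 (2.27 ± 0.28) and Slco1a4 (2.09 ± 0.26). NRF2 targets rose in 11 of 13 genes (11 adjusted over the list alone, mean 1.24, adjusted p = 5.39e-12), with Gpx2 (2.43 ± 0.39), Hmox1 (2.08 ± 0.26), Me1 (1.70 ± 0.35) and Nqo1 (1.70 ± 0.52).

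Amino acid catabolism fell in 16 of 21 genes (17 adjusted over the list alone, mean -1.12, adjusted p = 2.27e-13), including Sds (-4.18 ± 0.66), Cth (-2.09 ± 0.23), Bhmt (-1.93 ± 0.27) and Gnmt (-1.69 ± 0.31). Glucose handling fell in 6 of 12 genes (6 adjusted over the list alone, mean -0.68, adjusted p = 9.75e-04), including Pfkfb1 (-1.59 ± 0.31) and Pygl (-1.55 ± 0.18), the liver glycogen phosphorylase. Cyp7a1 (-4.66 ± 0.63), the rate-limiting enzyme of bile acid synthesis, fell from a signal of 146.7 ± 94.9 (SD, n = 4) to 2.33 ± 0.385 (SD, n = 5). Of the fatty acid synthesis list, Scd (-3.03 ± 0.46) and Srebf1 (-2.53 ± 0.32) fell while Me1 (1.70 ± 0.35) and Fasn (1.17 ± 0.31) rose, and the list was not called (mean -0.32, adjusted p = 0.579). Other falls were Car3 (-3.39 ± 0.54), carbonic anhydrase, Serpina6 (-2.32 ± 0.24), the corticosteroid carrier, Dusp1 (-2.66 ± 0.48) and Spink1 (-2.26 ± 0.45). The acute phase genes Lcn2 (2.47 ± 0.40) and Lbp (1.73 ± 0.25) rose, but their list did not hold (mean 0.31, adjusted p = 0.0473, but adjusted p = 0.389 with an estimated correlation).

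Other list shifts with R2 were lost with an estimated correlation. Growth hormone and IGF genes were lower (mean -0.62, adjusted p = 0.0348), with Ghr (-1.22 ± 0.18) and Igf1 (-1.04 ± 0.19), as were male-predominant genes (mean -0.75, adjusted p = 0.0154), with Hao2 (-1.94 ± 0.39). Fatty acid oxidation was higher (mean 0.26, adjusted p = 0.0104), with Ech1 (1.74 ± 0.15) and Acaa1b (1.19 ± 0.29), and so were p53 targets (mean 0.54, adjusted p = 0.0473), with Gdf15 (1.52 ± 0.43) and Mdm2 (1.49 ± 0.24). Adjusted p was 0.0665, 0.287, 0.0619 and 0.174 with an estimated correlation, in the same order. The test called 974 probe sets, 473 higher and 501 lower. R2 replicates 1 and 2 lay apart from the other 3 on the fourth principal component, and without both, as chosen after seeing the data, 662 were called. Leaving out single arrays ended the call of Nqo1 (without vehicle replicates 1 or 2, adjusted p up to 0.0895). Without R2 replicates 1 and 2 the calls of Nqo1, the acute phase list and the male-predominant list ended. List calls ended by leaving out single arrays included those of p53 targets (without R2 replicates 3, 4 or 5 or vehicle replicates 1 or 2, adjusted p up to 0.0959). Acute phase proteins (without R2 replicates 1, 2 or 3 or vehicle replicates 1 or 2, adjusted p up to 0.12) also lost significance. Growth hormone and IGF genes (without R2 replicate 3 or vehicle replicate 1, adjusted p up to 0.0601) did too.

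R2 at 300 and R1 at 100 mg/kg/day, the highest 24 h doses, differed in dose and study, so their values stand side by side without a matched dose. Their calls, which share no vehicle arrays, had 197 probe sets higher in both (expected 18.7 from independent lists), 88 lower in both (expected 12.2) and 2 in opposite directions (expected 31.4). Probe sets are not independent replicates, and over all of them the fold changes correlated across probe sets at Pearson's r = 0.574. The difference between the effects, R2 minus R1, was -0.04 (95% interval -0.50 to 0.41) for the cholesterol score, 0.04 (95% interval -0.24 to 0.32) for CAR and PXR targets, 0.09 (95% interval -0.30 to 0.47) for NRF2 targets and 0.12 (95% interval -0.13 to 0.36) for the proteasome. For the growth hormone and IGF score it was -0.75 (95% interval -1.19 to -0.31), with a camera adjusted p = 0.111.

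No single difference between the compounds passed the test. That of Socs2 was -3.37 ± 0.73 (adjusted p = 0.0862), that of Cyp7a1 was -3.22 ± 1.00 (adjusted p = 0.309) and that of Cyp2b2 was 1.36 ± 0.45 (adjusted p = 0.316). The vehicles of studies 4 and 1 themselves differed in Socs2 and Cyp2b2, by 2.52 ± 0.53 and -1.70 ± 0.32, and Cyp7a1 was at 1.51 ± 0.72, not called. These levels enter the values. limma called 0 probe sets, with 586 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0502. Interferon genes (mean 0.76, adjusted p = 2.75e-04) and acute phase genes (mean 0.28, adjusted p = 0.0352) were higher with R2 than with R1. Cell cycle (mean -0.72, adjusted p = 2.75e-04) and male-predominant genes (mean -0.60, adjusted p = 0.0264) were lower. Adjusted p was 0.28, 0.508, 0.328 and 0.508 with an estimated correlation, in the same order. The count was 1 without R1 replicate 1, 2 without study 1 vehicle replicate 3, 9 without R2 replicate 4, and 2 without study 4 vehicle replicate 2 or 3. It was 2 without the trend, 3 with no filter on dim probe sets and 6 with weighted arrays. Of these lists, 1 left-out array ended the calls of acute phase proteins (without study 1 R1 100 replicates 1 or 2 or study 1 vehicle replicates 2 or 3 or study 4 R2 300 replicates 1 or 2 or study 4 vehicle replicates 1 or 2, adjusted p up to 0.106). The cell cycle (without study 1 R1 100 replicate 2, adjusted p up to 0.0552) also lost significance. Male-predominant genes (without study 1 R1 100 replicate 3 or study 1 vehicle replicate 3 or study 4 R2 300 replicates 1, 2 or 3 or study 4 vehicle replicate 2, adjusted p up to 0.0934) did too. Without R2 replicates 1 and 2 those of acute phase and male-predominant genes ended.

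**Figure D4:**
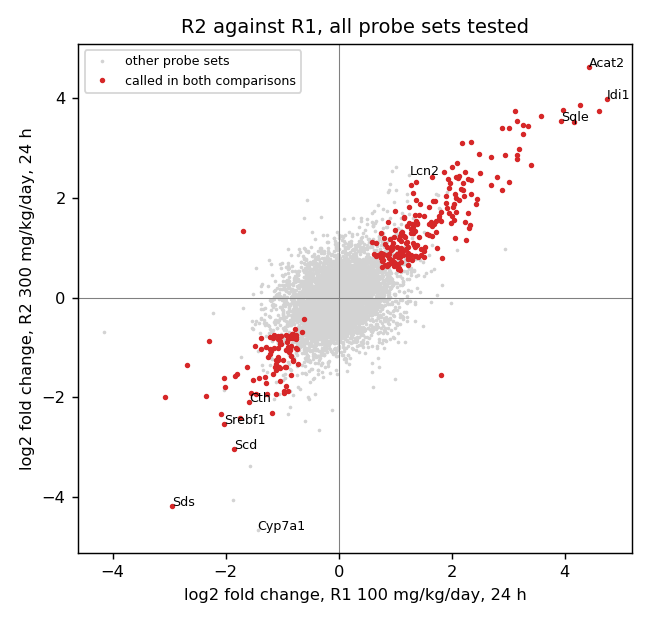
Log2 fold change of every tested probe set for R1 at 100 mg/kg/day (x axis) and R2 at 300 mg/kg/day (y axis) after 24 h, each against its own vehicle. Red points, called in both comparisons, number 197 in the upper right and 88 in the lower left, and 2 lie in the other quadrants.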

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

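Of the tests of explanations given here, those of an array of another group and of shuffled residuals were set before their results were seen, and the others were chosen only after. In groups of 4 or 5 arrays, an array counts as far from the others when its gap to the nearest of them takes up most of the group's range, which chance does in about 1 in 20 groups. Of 85 groups of list scores 7 had such an array, with these gaps in log2: CAR and PXR targets in R1 10 at 24 h (replicate 4, 0.21), fatty acid oxidation in the study 2 vehicle (replicate 1, -0.25), the proteasome in R1 20 at 336 h (replicate 1, 0.22), the proteasome in R1 100 at 336 h (replicate 2, -0.48), NRF2 targets in R1 30 at 336 h (replicate 3, 0.32), erythroid genes in R1 30 at 336 h (replicate 3, -0.73) and the proteasome in the study 4 vehicle (replicate 3, -0.11). Of 375 groups of log2 signals of named genes 18 had one. The gaps were those of Abcc2 in the study 3 vehicle (replicate 4, -0.67), Apoa4 in R1 20 at 336 h (replicate 5, -0.41), Ctsd in the study 3 vehicle (replicate 4, -1.42), Cyp1a2 in R1 100 at 336 h (replicate 1, -0.75), Cyp1a2 in the study 3 vehicle (replicate 5, -0.85) and Cyp51 in R1 20 at 336 h (replicate 2, -0.57). The others were Ehhadh in R1 20 at 336 h (replicate 3, -0.86), Ggt1 in R1 30 at 336 h (replicate 3, 0.61), Ggt1 in the study 3 vehicle (replicate 3, 0.55), Hal in R1 100 at 336 h (replicate 1, -0.57), Hao2 in R1 30 at 336 h (replicate 3, -2.72), Hao2 in the study 3 vehicle (replicate 5, 0.95), Mmp14 in R1 10 at 24 h (replicate 4, 0.63), Mvd in R1 100 at 336 h (replicate 2, -1.44), Mvd in the study 4 vehicle (replicate 1, -0.74), Phgdh in R2 300 at 24 h (replicate 2, -0.27), Psat1 in R1 30 at 336 h (replicate 3, 0.89) and Srebf1 in R1 10 at 24 h (replicate 4, -0.37).

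The effect of R1 at 100 mg/kg/day differed between 336 h and 24 h by limma's test of the difference, where time and study cannot be told apart. It called 337 probe sets, as many as in 1 of 100 shuffles of the residuals, the real order included, with 85 in the highest other. This argues against chance without excluding it. The log2 effect was higher at 336 h for Acat2 (2.11), Bhmt (1.86), Cth (1.31), Cyp1a1 (1.57, near background and lost without most single arrays), Cyp3a23-3a1 (0.90), Ddc (4.74), Fdft1 (1.11), Ggt1 (4.33), Gsta3 (3.46), Gstp1 (2.36), Msmo1 (1.63), Srebf1 (1.86) and Tsc22d1 (2.64). Treated means of Cyp3a23-3a1 (11571 at 24 h, 12134 at 336 h) lay near the top of the common scale. Its difference rests mostly on the vehicles (2530 and 1470), as do those of Ddc (158.7 and 3.78) and Acat2 (80.0 and 5.72). Bhmt, Cth, Srebf1 and Tsc22d1 are listed because they fell at 24 h. The effect was lower for Abcb4 (-1.49), Acot1 (-4.59), Acot2 (-6.40), Agxt (-1.32), Asl (-1.49), Bmal1 (-1.65), Cpt1a (-3.22), Cyp2c11 (-3.13), Cyp4a1 (-3.51), Ech1 (-3.82), Eci1 (-4.41), Ehhadh (-3.03), Igfbp3 (-1.63), Obp3 (-4.53), Plin2 (-2.40), Por (-2.72), Psma5 (-0.94) and Psmc4 (-0.84), where a lower effect can be a larger fall. List shifts, with adjusted p with an estimated correlation, were fatty acid oxidation (-1.90, adjusted p = 4.82e-10), fatty acid synthesis (0.85, adjusted p = 0.364), lipid droplet genes (-0.86, adjusted p = 0.084), cholesterol synthesis (0.57, adjusted p = 0.364), heat shock proteins (-1.04, adjusted p = 0.084), the cell cycle (-0.51, adjusted p = 0.364), growth hormone and IGF genes (-0.92, adjusted p = 0.084), oxidative phosphorylation (0.28, adjusted p = 0.267) and the proteasome (-0.63, adjusted p = 0.032).

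The effect of 30 mg/kg/day differed between the times in 61 probe sets, against 7 in the highest of the other shuffles. Of 100 shuffles, the real order included, 1 gave as many, which argues against chance here too without excluding it. It was higher at 336 h for Abcc3 (2.12), Aldh1a1 (2.10), Cyp2b2 (2.23), Defb1 (2.56), Ggt1 (4.40), Gpx2 (3.22), Gsta3 (2.53) and Gstp1 (3.41), and lower for Apoa4 (-2.83), Hsd17b6 (-1.93), Msmo1 (-1.34) and Socs2 (-2.94). The list shifts, with adjusted p with an estimated correlation, were NRF2 targets (0.70, adjusted p = 0.192), cholesterol synthesis (-1.01, adjusted p = 0.0194), lysosome genes (0.34, adjusted p = 0.192), the cell cycle (-0.64, adjusted p = 0.216), growth hormone and IGF genes (-0.57, adjusted p = 0.0656), stellate cell markers (-0.46, adjusted p = 0.34) and erythroid genes (-1.23, adjusted p = 0.0194).

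Fatty acid oxidation genes were lower at R1 100 mg/kg/day than in the vehicle arrays of study 2 after 336 h. Unusual vehicle arrays alone are argued against, since the score at 100 also lay -1.32 ± 0.08 (SE) from that at 20 mg/kg/day. A single array is argued against by the highest adjusted p without 1 array, 2.00e-24. A raised level of these genes in study 2 as a whole, brought down by the compound, stays open: the score at 100 was -0.35 from the vehicle of study 3, and the vehicle of study 2 was 1.23 ± 0.08 above it. An effect of dose and time also stays open and untested, because 100 mg/kg/day was given for 336 h in study 2 alone, and these explanations cannot be told apart.

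Gstp1 and Ggt1, which bile duct cells also express, were higher at R1 30 mg/kg/day after 336 h. A larger share of bile duct cells as the whole cause is argued against only weakly. The 4 cholangiocyte markers, none of them in another list, were higher by 0.82 ± 0.23 on average and Gstp1 rose by 3.71 ± 0.23. Epcam (1.30) and Cd24 (1.56) rose, and Krt19 (0.16) and Cftr (0.27) were not called, and all 4 have signal in the vehicle liver as well, with means of 38.1, 12.5, 13.6 and 10.1. Signal shared with near-identical family members stays open, since 3 tested probe sets of both genes rose and no value here parts the members of these families. An effect of the compound on liver cells also stays open as a hypothesis.

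R1 30 mg/kg/day replicate 3 at 336 h lay apart from its group in the NRF2 and erythroid scores and in Ggt1, Hao2 and Psat1, where chance sets an array apart in about 1 in 20 groups. An array of another group under its label is argued against, since its median correlation with its own group was 0.964, 0.0243 above the highest with another group (0.94, R1 100 at 336 h). Pancreas or adipose tissue in the sample is argued against, because its score of these markers lay -0.19 from the highest other array of the group. Its blood score was low and is part of what set the array apart, so it tests nothing here. A stronger response of 1 sample stays open, and the design gives no group that would test it.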

How the results depend on the processing

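Arrays weighted by quality, centring on the tested probe sets, and R2 without replicates 1 and 2 were chosen only after the data were seen. Counts of called probe sets, with the lowest and highest on leaving out 1 array, were R1 10 at 24 h 79 (37 to 95), R1 30 at 24 h 110 (73 to 110), R1 100 at 24 h 407 (263 to 376), R1 20 at 336 h 282 (208 to 272), R1 100 at 336 h 656 (546 to 662), R1 30 at 336 h 717 (453 to 672) and R2 974 (793 to 1093). For the other comparisons they were 100 against 10 253 (124 to 276), 100 against 20 259 (198 to 257), time at 100 337 (237 to 371), time at 30 61 (30 to 61), R2 against R1 0 (0 to 9), vehicles 4 and 1 359 (193 to 291) and vehicles 3 and 2 1135 (909 to 1090). With 1 probe set per gene, where fewer features are tested, counts were R1 10 at 24 h 34, R1 30 at 24 h 42, R1 100 at 24 h 221, R1 20 at 336 h 160, R1 100 at 336 h 373, R1 30 at 336 h 405, R2 579, 100 against 10 157, 100 against 20 139, time at 100 186, time at 30 34, vehicles 4 and 1 161 and vehicles 3 and 2 611. With weighted arrays they were R1 100 at 24 h 633, R1 20 at 336 h 452, 100 against 10 380, R2 against R1 6 and vehicles 4 and 1 714, and the cause was not tested. For R2 against R1, where limma called 0, the count was 2 without the trend, 3 with no filter, 2 with the strict filter, 2 with the larger offset and 2 with centring on the tested probe sets, and the cause was not tested. Effects between studies have no single-study fit. Other counts moved less under these settings, the smaller offset and each study fitted alone, and R2 without replicates 1 and 2 gave 662, ended 18 gene and 4 list calls and added 1 and 1. No called gene or list changed direction under any alternative run.

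Of results for named genes on leaving out 1 array, 4561 kept their side of the threshold, 496 lost a call and 14 gained one, and of those for lists 4265, 91 and 64. An estimated correlation ended 58 list calls and left 418 results as they were. Each study fitted alone ended 57 gene calls, with fewer arrays behind the spread, no filter 28, weighted arrays 12, the smaller offset 10 and the larger 2. Centring each array on the median of all its values and quantile normalization changed nothing by construction, since every array already held the same values, so they say nothing about stability. Signal near the array's background limits the folds of dim genes, which the offset draws towards 0.

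Replicate numbers do not pair the samples: the deviations of same-numbered arrays correlated at 0.03, 0.05, -0.02 and -0.01 on average in studies 1 to 4, and 2 of 18, 2 of 12, 0 of 4 and 0 of 4 pairs correlated above 0.1. With a replicate block the counts were R1 10 at 24 h 94, R1 30 at 24 h 109, R1 100 at 24 h 412, R1 20 at 336 h 283, R1 100 at 336 h 664, R1 30 at 336 h 642, R2 1025, 100 against 10 264, 100 against 20 205, time at 100 327, time at 30 55 and R2 against R1 1. It ended 34 gene and 9 list calls and added 6 and 3. For vehicles between studies no blocked value can be had, because the blocks lie within studies.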

Other observations

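The tests of explanations for the vehicle difference, with their genes, were chosen only after the result was seen, and the counts of splits before. Phgdh and Psat1, enzymes of serine synthesis, were called in part of the comparisons with vehicle. Phgdh rose: 1.33 ± 0.39 with R1 20 at 336 h, 1.34 ± 0.41 with R1 100 at 336 h, 1.98 ± 0.39 with R1 30 at 336 h and 1.40 ± 0.39 with R2. It was not called at 0.24 ± 0.44 (R1 10 at 24 h), 0.72 ± 0.47 (R1 30 at 24 h) and 1.05 ± 0.47 (R1 100 at 24 h). Psat1 rose: 2.07 ± 0.46 with R1 100 at 24 h, 1.76 ± 0.38 with R1 30 at 336 h and 1.99 ± 0.38 with R2. It was not called at 0.67 ± 0.43 (R1 10 at 24 h), 1.13 ± 0.46 (R1 30 at 24 h), 0.43 ± 0.38 (R1 20 at 336 h) and 1.16 ± 0.40 (R1 100 at 336 h). They are single genes of the ER stress and integrated stress response list, which was not called in any comparison with vehicle (smallest adjusted p 0.195). With R2, Trib3 (1.75 ± 0.45), Asns (0.89 ± 0.22) and Atf3 (0.83 ± 0.29) of that list rose as well. Abcb4, which carries phospholipid into bile, rose by 0.80 ± 0.24 with R1 100 at 24 h and by 1.19 ± 0.20 with R2, but fell with R1 100 at 336 h (-0.70 ± 0.21). It was not called at 0.39 ± 0.22 (R1 10 at 24 h), 0.52 ± 0.24 (R1 30 at 24 h), -0.24 ± 0.20 (R1 20 at 336 h) and 0.39 ± 0.20 (R1 30 at 336 h). Abcc2, which carries conjugates into bile, rose by 0.80 to 1.72 in 6 of 7 comparisons with vehicle and was not called at 0.34 ± 0.27 (R1 10 at 24 h), while their list was not called in any comparison with vehicle (smallest adjusted p 0.171). The call of Abcc2 with R2 ended without R2 replicates 1 and 2. Leaving out 1 array ended the calls of Abcc2 with R1 30 at 24 h (without vehicle replicate 1, adjusted p up to 0.117), Abcc2 with R1 100 at 24 h (without vehicle replicate 1, adjusted p up to 0.0614), Abcc2 with R1 20 at 336 h (without R1 replicates 1, 2, 4 or 5 or vehicle replicates 1, 2, 3 or 4, adjusted p up to 0.136), Phgdh with R1 20 at 336 h (without R1 replicates 1, 3 or 5 or vehicle replicates 2, 3 or 4, adjusted p up to 0.129), Phgdh with R1 100 at 336 h (without R1 replicates 3 or 4 or vehicle replicates 2, 3 or 4, adjusted p up to 0.172), Psat1 with R1 100 at 24 h (without R1 replicate 1, adjusted p up to 0.0556), Atf3 with R2 (without R2 replicates 3 or 5 or vehicle replicates 1, 2 or 3, adjusted p up to 0.16), Abcb4 with R1 100 at 24 h (without R1 replicates 1 or 3 or vehicle replicates 1 or 2, adjusted p up to 0.27) and Abcb4 with R1 100 at 336 h (without R1 replicates 1 or 3 or vehicle replicates 2 or 3, adjusted p up to 0.0879).

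Cyp1a2, a cytochrome P450 under AhR control, fell: -1.10 ± 0.26 with R1 20 at 336 h, -1.42 ± 0.28 with R1 100 at 336 h, -1.33 ± 0.26 with R1 30 at 336 h and -0.82 ± 0.26 with R2. At 24 h it was not called with R1, at 0.19 ± 0.30 (R1 10 at 24 h), -0.20 ± 0.32 (R1 30 at 24 h) and -0.38 ± 0.32 (R1 100 at 24 h). Cyp1a1, also under AhR control, was called only with R1 100 at 336 h (1.46 ± 0.32) among comparisons with vehicle. Its signal was 14.4 there and 1.46 to 4.97 on average in the other groups, under the filter level of 9.17, so the call gives a direction and no reliable size. Their list was not called in any comparison with vehicle (smallest adjusted p 0.184). The clock gene Bmal1 fell too: -0.80 ± 0.23 with R1 20 at 336 h, -2.08 ± 0.24 with R1 100 at 336 h and -0.90 ± 0.23 with R1 30 at 336 h. It was not called at -0.01 ± 0.26 (R1 10 at 24 h), -0.26 ± 0.28 (R1 30 at 24 h), -0.42 ± 0.28 (R1 100 at 24 h) and -0.40 ± 0.23 (R2). The clock list was not called in these comparisons or the others with vehicle (smallest adjusted p 0.505). The collagen genes Col1a1 (-1.51 ± 0.42) and Col3a1 (-1.02 ± 0.24) and the endothelial receptor gene Kdr (-1.19 ± 0.25) fell with R1 30 at 336 h, where the stellate cell list was not called (mean -0.40, adjusted p = 0.0626). Hepatocyte identity genes, among them albumin, were not called as a list in any comparison with vehicle (smallest adjusted p 0.144). The calls of these genes ended without 1 array for Cyp1a2 with R2 (without R2 replicate 3 or vehicle replicates 1, 3 or 4, adjusted p up to 0.0984), Bmal1 with R1 20 at 336 h (without R1 replicates 3 or 5 or vehicle replicates 1, 3 or 4, adjusted p up to 0.103) and Col1a1 with R1 30 at 336 h (without vehicle replicate 2, adjusted p up to 0.0704).

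A hypothesis on the vehicle arrays of study 2 is a food state nearer to fasting, in which fatty acid oxidation genes run high and sterol synthesis low. Known fasting genes, signed by their response, were 0.82 ± 0.24 higher in study 2 than in study 3 over 5 genes. Igfbp1 (-2.36, study 3 minus 2) and Pklr (1.92) differed that way, and Pck1 (-0.06), Tat (0.31) and Irs2 (-0.06) were not called, so this may be a cause and stays open. For another time of day of sampling, limma called 0 of 7 clock genes, with 2 at an unadjusted p under 0.05, Dbp at -1.01 ± 0.43 and Per2 at 0.84 ± 0.36 (adjusted p = 0.104 and 0.104), which leaves it open as well.

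Other splits of the compared arrays were counted for 11 comparisons, and shuffles of the residuals for the 3 differences between effects. Of the 35 splits for 4 comparisons, 1, the real one, called as many probe sets. This argues against chance there, but so few splits cannot exclude it. The real count and the highest of the other splits were R1 10 at 24 h 79 against 45, R1 100 at 336 h 656 against 92, 100 against 10 253 against 154 and vehicles 4 and 1 359 against 91. Of 100 splits drawn for 5 further comparisons, 1, the real one, called as many, which argues against chance without excluding it. These counts were R1 20 at 336 h 282 against 185, R1 30 at 336 h 717 against 357, R2 974 against 812, 100 against 20 259 against 149 and vehicles 3 and 2 1135 against 670. With 3 arrays in both groups, the 10 splits are too few for R1 30 at 24 h (110, highest other 0) and R1 100 at 24 h (407, highest other 2). For R2 against R1, limma called 0 with 586 at an unadjusted p under 0.05, and the 100 shuffles of the residuals called up to 38. Since no count can be under 0, 100 of 100 gave as many by construction, and this says nothing about chance.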
